A study of Homo sapiens with 7 samples.

How the data were processed

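Gene expression was measured in human soft tissue surrounding dental implants, taken either at healthy implants or at implants with peri-implantitis, an inflammatory disease in which the soft tissue is inflamed and supporting bone is lost. The series describes 7 samples, 3 healthy and 4 peri-implantitis, from 3 healthy controls and 4 patients per the labels' design text. The p-values measure the spread between these arrays, which is between people if the arrays are as labelled and can be technical otherwise. Per the labels' protocols, healthy tissue came from procedures such as reshaping the soft tissue around healed implants with provisional crowns, and diseased tissue from surgery for peri-implantitis. The kind of procedure and the disease group therefore cannot be told apart in this design. Per the same protocols, pieces were trimmed, kept cold in an RNA stabiliser and total RNA was purified on spin columns.

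Biotin-labelled RNA was hybridised to a 1-colour Affymetrix array whose probes lie in exons shared by most transcripts of a gene, per the labels' protocols. The deposited values are log2 SST-RMA signals, made by the authors with Transcriptome Analysis Console per the labels and the submitters' processing notes. The labels' design text also names the Affymetrix Exon Array Computational Tool. In general, SST-RMA is a form of robust multichip averaging with a signal space transformation. It corrects background, stretches the signal range, normalizes between arrays and gives 1 value per probe set. The software version, the reference set of the normalization and the array annotation are not given in the sources used here, and neither are slide or scan batches. The sample titles name wells. Healthy arrays were in rows A to C and the peri-implantitis arrays analysed in rows D to F of the same column. Group and well row therefore cannot be told apart. The scale was taken as log2 from the range of values, which runs to 19.9 with a median of about 6.8 on each array. For 1 peri-implantitis sample the column of the value table held no values, and it was not analysed here, so that every comparison was of 3 healthy against 3 peri-implantitis arrays rather than the 3 against 4 for which the design had been fixed. The test itself was kept.

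The value table held 24351 probe sets. Of these, 2903 were controls (612 negative controls, 2197 positive controls, 63 ERCC controls and 31 other Affymetrix controls) and stayed out of the tests. XIST, TSIX and genes of the Y chromosome were also left out, because the samples came from people. The remaining 21371 probe sets were tested. The platform annotation gave 1 gene symbol for each of 17709 probe sets and several for none, while 3739 non-control probe sets had no gene there and are unnamed here. All 17709 gene identifiers were matched to current RefSeq symbols. After the exclusions, 17682 tested probe sets carried a symbol. Genomic coordinates are not given because the sources name no build for the probe sets.

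Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes on the deposited log2 values, group as the only term, 4 residual degrees of freedom). P-values were adjusted by the Benjamini-Hochberg method over all 21371 probe sets, and a gene was called at an adjusted p under 0.05. Differences are peri-implantitis minus healthy on the log2 scale, so that 1 is a 2-fold higher signal. Standard errors and 95% intervals come from the same fit and are not adjusted for the number of genes. The prior of eBayes, with 5.90 degrees of freedom, widens the intervals of genes that vary very little and narrows those of genes that vary most. No detection calls were used, so a probe set was described as above background when its mean exceeded 7.97, the 95th percentile of the negative controls over all arrays. The number of arrays limits the precision.

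In all, 44 gene lists were fixed before the data were examined. They covered epithelial structures, leukocytes, stromal cells, tissues that a biopsy could include by accident, and pathways of inflammation, matrix turnover, bone and metabolism. Each gene was represented by its probe set with the highest mean. Lists with at least 5 measured members were tested with camera in limma at a preset correlation of 0.01, and beside it with an estimated correlation and with fry, which asks whether a list's genes move one way without comparing them with other genes. For the members of each list, calls adjusted over all probe sets are given together with calls adjusted over the list alone.

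Genes named in the text follow a rule fixed at the same time. It takes the 10 largest log2 differences in each direction among called genes. Because no gene was called, the rule's second step applied: the largest differences among genes at an unadjusted p under 0.01 whose healthy and peri-implantitis values did not overlap. It adds up to 4 members of each list with the smallest p, and further list members given as examples that did not pass. All list members at an unadjusted p under 0.05 are named, a choice made after their values were seen. Symbols of uncharacterised loci, pseudogenes, immunoglobulin and T cell receptor segments, and genes often deleted in people were not named.

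The whole procedure was tested on simulated data with the means of the tested probe sets. Noise was drawn independently for each gene, with the variances moderated by eBayes rather than the probe sets' own. Recovery in the real data can therefore differ and may be lower. For this comparison of 3 arrays against 3, limma recovered 188 of 200 simulated 2-fold changes among 21371 probe sets, with 13 false calls, and 0 of 200 simulated 1.5-fold changes. A simulated shift of 0.2 in the 37 genes of 1 list was recovered by camera at an adjusted p of 3.4e-07, with 0 other lists called. Estimated correlations within the real lists reached 0.303, which the simulated noise did not have. Shifts in shorter lists, such as the 7 melanocyte genes, were not simulated. The result therefore does not show what camera could find in such lists. The alternatives tried were a repeated quantile normalization, a shift of each array to a common median, leaving out the dimmest 30% or 50% of probe sets, eBayes with trend and robust settings, array weights, only named probe sets, averaging a gene's probe sets, other thresholds and set tests, and leaving out each array in turn.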

Results

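Transcript levels were measured by array in the soft tissue barrier around dental implants, the epithelium and connective tissue that seal the implant against the mouth. The arrays analysed were 3 from healthy implants and 3 from implants with peri-implantitis, an inflammatory disease with loss of the supporting bone. The median signal of the 21371 tested probe sets lay between 6.76 and 6.82 (log2) on the 6 arrays, and the interquartile range between 3.87 and 4.01. Between 34.3% and 38.2% of probe sets exceeded the 95th percentile of the negative controls on their own array.

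The arrays carried the transcripts of a stratified oral mucosa. All 9 measured basal keratinocyte markers, 28 of 37 genes of the cornified envelope and suprabasal keratins, 16 of 18 genes of desmosomes and adherens junctions and 11 of 13 junctional epithelium markers had a mean above 7.97, the 95th percentile of the negative controls. So did 18 of 21 fibroblast markers, 14 of 20 blood endothelial markers, 14 of 15 plasma cell markers and 14 of 20 monocyte and macrophage markers. None of the 17 salivary gland, 10 adipocyte, 9 Schwann cell and nerve or 7 melanocyte markers did, and 2 of 18 skeletal muscle markers did.

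The arrays of 1 group were as far from each other as from those of the other group. Pearson correlations lay between 0.9921 and 0.9931 for the 6 pairs within a group and between 0.9921 and 0.9933 for the 9 pairs between groups. These correlations are across probe sets, which are not independent replicates. At most 5 probe sets had identical values on both arrays of a pair, so no column was a copy of another. This does not tell separate samples from repeat arrays of one RNA, and the 6 arrays were counted separately because the labels describe separate samples. The SD of the log2 difference between 2 arrays averaged 0.335 within groups and 0.335 between groups. The median SD of a probe set was 0.173 over the healthy arrays and 0.182 over the peri-implantitis arrays. The 8 bacterial and phage spike-in controls had SDs of 0.0735 to 0.505 over the 6 arrays, with a median of 0.133. The SDs were 0.133, 0.310, 0.180 and 0.505 for dap, lys, phe and thr. For bioB, bioC, bioD and cre they were 0.0735 to 0.132. The 200 probe sets nearest in signal to each of them had median SDs of 0.119 to 0.253. Of the 8 spike-ins 2, lys and thr, varied more than the median of those probe sets. The step at which each control enters was not considered, so their SDs need not hold all technical noise.

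**Figure D1:**
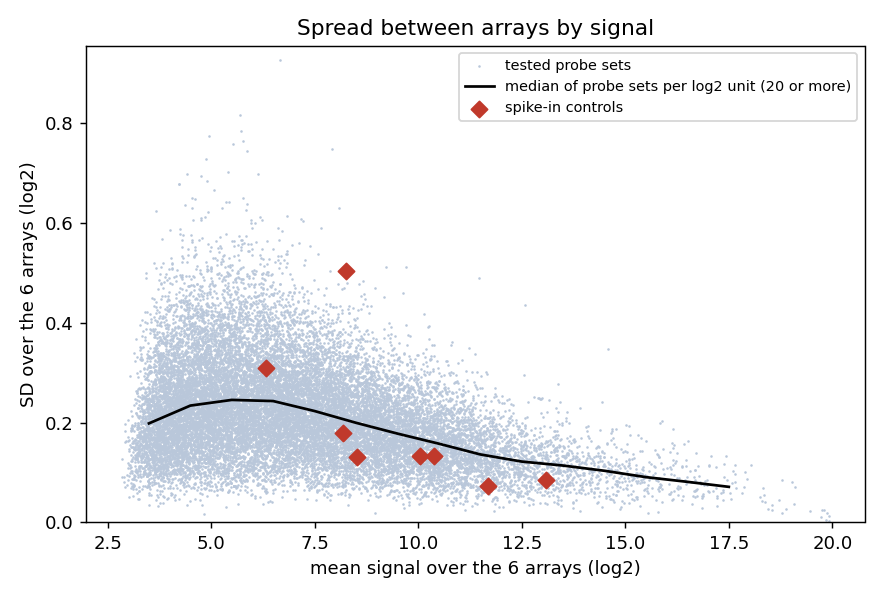
SD over the 6 arrays (log2, vertical axis) against mean signal over the 6 arrays (log2, horizontal axis) for each tested probe set, with the median per log2 unit of signal as a line and the 8 spike-in controls as diamonds. The spike-in with the highest SD, 0.505, lies at the upper edge of the probe sets of its signal, and the lowest spike-in SD is 0.0735.

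The main comparison asked which transcripts differ between peri-implantitis and healthy peri-implant soft tissue. No transcript passed the test in either direction. Among the 21371 probe sets, limma called 0 at an adjusted p under 0.05 and 0 at an adjusted p under 0.1, and the smallest adjusted p was 0.954. An unadjusted p under 0.05 was reached by 1028 probe sets, or 4.81%, where 1069 would be reached by chance; 506 of them had a higher and 522 a lower signal in peri-implantitis. The healthy and peri-implantitis values did not overlap in 2146 probe sets, or 10.04%, and chance gives 10% for 3 arrays against 3.

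The median size of the differences was 0.119 on the log2 scale and the 95th percentile was 0.387. A single probe set, that of LRRC38, reached a 2-fold difference, and 141 reached 1.5-fold, of which 6 had a mean above 7.97. The 95% interval of the difference excluded a 2-fold change in either direction for 21068 probe sets, or 98.6%, and a 1.5-fold change for 69.2%. Among probe sets with a mean above 7.97, these shares were 99.8% and 85.3%. All these shares describe the deposited values, which were not set against scanned signals here. It was also not tested whether the values belong to the labelled samples. If they do not, neither these shares nor the values of single genes and lists below say anything about the disease. The median half-width of the interval was 0.374 in the 25% of probe sets with the lowest signal and 0.326 in the 25% with the highest. With 200 genes changed in simulated data and p adjusted over all 21371 probe sets, limma recovered 0 of 200 changes of 1.5-fold and 188 of 200 changes of 2-fold. The simulated noise was independent between genes and had moderated variances, so recovery in the real data may be lower.

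**Figure D2:**
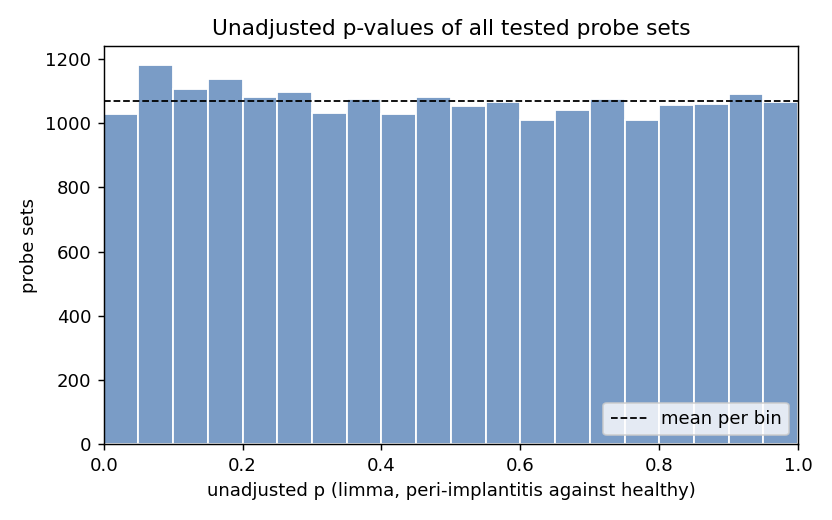
Number of probe sets (vertical axis) by unadjusted p from limma for peri-implantitis against healthy (horizontal axis, 20 bins of equal width); the dashed line marks the mean of 1069 per bin. Bins hold between 1010 and 1181 probe sets, and the bin nearest 0 holds 1028.

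The 20 genes that the rule picked out all missed the adjusted threshold, each at an adjusted p of 0.954 in limma, and 2 of them had a mean above 7.97. These were ELOB, which encodes a subunit of the elongin complex, and TAGAP, which encodes a GTPase-activating protein of activated T cells. ELOB had a mean signal of 7.87 ± 0.046 (SD, n = 3) in healthy and 8.67 ± 0.29 (SD, n = 3) in peri-implantitis tissue, a log2 difference of 0.81 with a standard error of 0.17. TAGAP had 9.32 ± 0.41 (SD, n = 3) and 10.1 ± 0.17 (SD, n = 3), a log2 difference of 0.78 with a standard error of 0.21. Among the 8 others with a higher mean in peri-implantitis were CDC45 and FOXM1, which act in DNA replication and in the cell division programme, with differences of 0.88 and 0.77. KLKB1, which encodes plasma prekallikrein, had 0.78, VPREB1, a surrogate light chain of immature B cells, had 0.78, and the beta-defensin gene DEFB131A had 0.78. DNAJC28, ARMCX6 and LACTB2 had 0.86, 0.81 and 0.77. Of the 10 genes with a lower mean, LRRC38 had a log2 difference of -1.01 with a standard error of 0.23. The progesterone receptor gene PGR had -0.74, the cyclin gene CCNA1 -0.73 and the receptor phosphatase gene PTPRO -0.77. ZNF135, DPH7, CHTF18, IGSF11, SLC6A16 and SLC9A5 had differences between -0.89 and -0.72.

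No call was made for any of the 44 gene lists. Camera in limma called 0 lists at an adjusted p under 0.05, the smallest being 0.351; 2 lists were under 0.05 before adjustment. With an estimated correlation camera called 0 lists, with 0 under 0.05 before adjustment and a smallest adjusted p of 0.924. Fry called 0 lists, with 2 under 0.05 before adjustment and a smallest adjusted p of 0.691. Those 2 were the tight and gap junction genes (unadjusted p = 0.0177 in fry) and the melanocyte genes (unadjusted p = 0.0409 in fry). The median log2 difference of a list was at most 0.159 in size. The median, the mean and the direction given by camera differed in sign in 8 lists, those of B cells, fibroblasts, adipocytes, basement membrane, chemokines, complement, hypoxia and glycolysis, and immediate early and heat shock genes. Of the 782 genes on the lists, the 95% interval excluded a 2-fold change for 774 and a 1.5-fold change for 611. Of these 782 genes, 451 had a mean above 7.97, and among them the interval excluded a 2-fold change for 450 and a 1.5-fold change for 404. For the others, signals near those of the negative controls limit what an interval says about the transcript. An unadjusted p under 0.05 was reached by 33 of the 782, where chance gives 39.1, with 13 higher and 20 lower in peri-implantitis, and all 33 are named with their lists. Adjusted over all probe sets, or over the 782 list genes together, 0 list members were called. Adjusting over each list alone does not allow for the number of lists, so a few calls can come by chance. By that adjustment 1 member was called in each of 3 lists, EPB42, ADAMTS5 and ATR. The healthy and peri-implantitis values of these 3 genes did not overlap, and all 3 had a mean below 7.97.

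**Figure D3:**
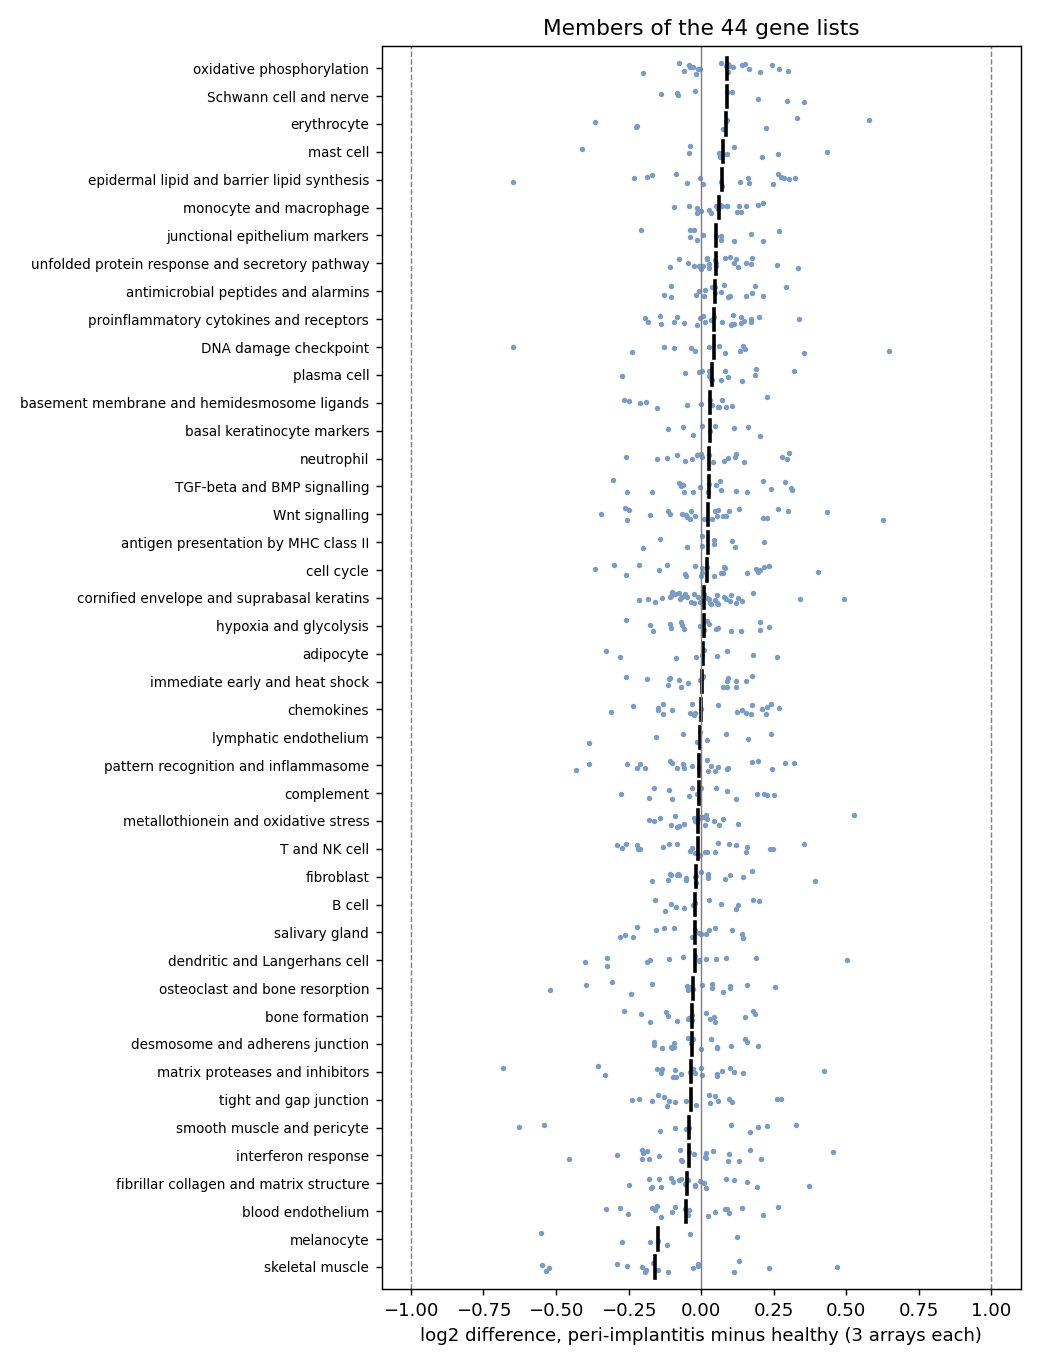
Log2 difference, peri-implantitis minus healthy, from 3 arrays each (horizontal axis), for each measured member (points) of the 44 gene lists (vertical axis, ordered by median); black bars mark list medians, and dashed lines a 2-fold difference either way. All members lie between the dashed lines, and the medians run from -0.159 for skeletal muscle to 0.0890 for oxidative phosphorylation.

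The epithelial barrier gave no difference that passed the test. Of the 37 genes of the cornified envelope and suprabasal keratins, 19 had a higher and 18 a lower mean in peri-implantitis, with a median difference of 0.011, and the 95% interval excluded a 1.5-fold change in 34. KRT13, the main suprabasal keratin of non-keratinised oral epithelium, had a signal of 18.3 ± 0.068 (SD, n = 3) in healthy and 18.2 ± 0.020 (SD, n = 3) in diseased tissue, a difference of -0.048 (95% interval -0.33 to 0.24). The cornified envelope precursor SPRR3 differed by -0.034 (-0.33 to 0.26), filaggrin (FLG) by -0.21 (-0.54 to 0.11), KRTDAP by 0.49 (0.08 to 0.90) and LCE3E by 0.34 (0.02 to 0.66). The medians were 0.031 for the 9 basal keratinocyte markers, -0.032 for the 18 genes of desmosomes and adherens junctions, -0.035 for the 18 tight and gap junction genes and 0.072 for the 19 barrier lipid genes, of which 5 had a mean above 7.97. PNPLA1, an enzyme of barrier lipid synthesis, had -0.65 (-1.26 to -0.03). DSP, which encodes the desmosomal plaque protein desmoplakin, differed by -0.094 (-0.39 to 0.20), the hemidesmosomal integrin gene ITGB4 by 0.20 (-0.14 to 0.55), and the tight junction genes CLDN4 and OCLN by 0.26 (-0.06 to 0.58) and -0.24 (-0.55 to 0.07). The 13 junctional epithelium markers had a median of 0.051. Among them ODAM, a secreted protein of the epithelial attachment, had 16.4 ± 0.080 (SD, n = 3) and 16.4 ± 0.018 (SD, n = 3), and AMTN differed by 0.27 (-0.06 to 0.60). FLG, AMTN and PNPLA1 had means below 7.97. None of these lists had a member called when adjusted over the list alone.

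Leukocyte markers also gave no call. The median differences were 0.029 for the 19 neutrophil, 0.061 for the 20 monocyte and macrophage, 0.039 for the 15 plasma cell, -0.021 for the 13 B cell, -0.012 for the 24 T and NK cell, -0.023 for the 15 dendritic and Langerhans cell and 0.074 for the 11 mast cell genes. Means above 7.97 were found for 11 of the neutrophil, 5 of the B cell, 8 of the T and NK cell, 2 of the dendritic and Langerhans cell and 4 of the mast cell genes. The neutrophil receptor genes CXCR2 and FCGR3B differed by 0.30 (95% interval -0.09 to 0.70) and 0.29 (-0.12 to 0.70). The complement component C1QC and lysozyme (LYZ), both abundant in macrophages, differed by 0.20 (-0.13 to 0.52) and 0.15 (-0.13 to 0.44). JCHAIN, which joins secreted immunoglobulin units, had 17.4 ± 0.076 (SD, n = 3) in healthy and 17.4 ± 0.12 (SD, n = 3) in diseased tissue. The B cell receptor component CD79A had 14.8 ± 0.084 (SD, n = 3) and 14.9 ± 0.12 (SD, n = 3). TNFRSF17, the plasma cell receptor BCMA, differed by 0.32 (-0.14 to 0.78), POU2AF1 by -0.27 (-0.65 to 0.10), and the T cell checkpoint gene CTLA4 by 0.35 (-0.05 to 0.75). In the mast cell list, HDC, the histamine-forming enzyme, had -0.41 (-0.73 to -0.09) and the stem cell factor receptor KIT 0.43 (0.10 to 0.77). In the dendritic and Langerhans cell list, the chemokine receptor gene XCR1 had -0.40 (-0.78 to -0.02) and the chemokine gene CCL22 0.50 (0.02 to 0.98). CTLA4, HDC, XCR1 and CCL22 had means below 7.97. No member of these 7 lists was called when adjusted over the list alone.

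Among inflammatory and innate immune genes, the medians were 0.046 for the 25 proinflammatory cytokines and receptors, -0.0019 for the 23 chemokines, -0.0062 for the 25 genes of pattern recognition and the inflammasome, -0.044 for the 23 interferon response genes, 0.048 for the 19 antimicrobial peptides and alarmins, -0.0090 for the 17 complement genes and 0.024 for the 10 genes of MHC class II antigen presentation. Means above 7.97 were found for 14 of the cytokine and receptor, 16 of the chemokine, 14 of the pattern recognition, 11 of the interferon response, 9 of the antimicrobial, 10 of the complement and 7 of the MHC class II genes. IL1B, a central cytokine of periodontal inflammation, had 12.5 ± 0.17 (SD, n = 3) in healthy and 12.5 ± 0.17 (SD, n = 3) in peri-implantitis tissue, a difference of -0.015 (95% interval -0.36 to 0.33). IL23A differed by 0.34 (-0.20 to 0.87) and the neutrophil chemokine CXCL8 by 0.17 (-0.15 to 0.50). The monocyte chemokine CCL7 differed by -0.31 (-0.63 to 0.01), and the alarmin S100A8 by 0.093 (-0.19 to 0.38). The nucleic acid sensors TLR7 and TLR9 had -0.43 (-0.73 to -0.14) and -0.39 (-0.68 to -0.09). The interferon-induced genes RSAD2 and IFI44L had -0.46 (-0.85 to -0.06) and 0.46 (0.01 to 0.90). The lipocalin gene LCN2 had 0.29 (-0.16 to 0.74). IL23A, CCL7, TLR7, TLR9, RSAD2 and IFI44L had means below 7.97. None was called over all probe sets or over its list alone.

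In the connective tissue, vessels and bone, 1 gene was called when adjusted over its list alone and 0 over all probe sets. That gene was ADAMTS5, an aggrecan-degrading protease, with 6.01 ± 0.25 (SD, n = 3) in healthy and 5.33 ± 0.10 (SD, n = 3) in diseased tissue. Its log2 difference was -0.68 (95% interval -1.04 to -0.32), with an adjusted p of 0.0377 over the 22 matrix proteases and inhibitors and 0.954 over all probe sets in limma. The related ADAMTS4 had -0.35 (-0.69 to -0.02) and MMP19 had 0.42 (0.01 to 0.83). The collagenase MMP13 had 14.3 ± 0.13 (SD, n = 3) and 14.2 ± 0.12 (SD, n = 3), and the gelatinase MMP9 differed by -0.029 (-0.48 to 0.42). The median of the protease list was -0.034. Medians were -0.050 for the 22 fibrillar collagen and matrix genes, 0.032 for the 15 basement membrane genes, -0.018 for the 21 fibroblast markers, -0.052 for the 20 blood and -0.0028 for the 9 lymphatic endothelial markers and -0.041 for the 11 smooth muscle and pericyte markers. COL1A1, the main collagen chain of gingival connective tissue, had 13.8 ± 0.13 (SD, n = 3) and 13.8 ± 0.059 (SD, n = 3). COL12A1 differed by -0.17 (-0.46 to 0.11), the transcription factor gene TWIST1 by 0.39 (0.03 to 0.75) and the angiopoietin receptor gene TEK by -0.33 (-0.64 to -0.01). In the smooth muscle and pericyte list, the leiomodin gene LMOD1 had -0.63 (-1.06 to -0.19) and the desmin gene DES -0.54 (-1.003 to -0.08). For osteoclasts and bone resorption the median was -0.029 over 17 genes, and for bone formation -0.032 over 17, with means above 7.97 for 6 and 7 of them. The osteoclast genes ATP6V0D2 and CALCR had -0.52 (-0.92 to -0.12) and -0.40 (-0.76 to -0.04). Both had means below 7.97, as did ADAMTS5, ADAMTS4, MMP19, TWIST1, TEK, LMOD1 and DES. Above 7.97 were 3 of the lymphatic endothelial and 6 of the smooth muscle and pericyte markers.

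The remaining pathways gave medians of 0.089 for the 22 genes of oxidative phosphorylation, 0.0086 for the 19 of hypoxia and glycolysis, 0.049 for the 24 of the unfolded protein response and secretory pathway, 0.020 for the 25 of the cell cycle, -0.0095 for the 22 of metallothioneins and oxidative stress, 0.0021 for the 19 immediate early and heat shock genes, 0.024 for the 28 of Wnt signalling and 0.027 for the 22 of TGF-beta and BMP signalling. MT2A, a metal-binding metallothionein, had 17.0 ± 0.071 (SD, n = 3) and 17.0 ± 0.064 (SD, n = 3), and SRXN1, which reduces oxidised peroxiredoxins, differed by 0.53 (95% interval 0.17 to 0.88). The Wnt enhancer RSPO3 differed by 0.63 (0.24 to 1.01) and the ligand gene WNT10A by -0.35 (-0.69 to -0.01). The cyclin gene CCNB1 had 0.40 (0.06 to 0.74). ID3 and ID2, target genes of BMP signalling, had 0.31 (0.02 to 0.60) and -0.31 (-0.59 to -0.02). SRXN1, RSPO3, WNT10A, CCNB1, ATR and BRCA1 had means below 7.97, as did all but 5 of the Wnt signalling genes and all but 9 of the cell cycle genes. In the DNA damage checkpoint list, with a median of 0.044 over 14 genes, the checkpoint kinase gene ATR had 6.22 ± 0.096 (SD, n = 3) and 5.57 ± 0.26 (SD, n = 3). Its difference was -0.65 (-1.01 to -0.29), with an adjusted p of 0.0358 over the list alone and 0.954 over all probe sets in limma. The DNA repair gene BRCA1, on the same list, had a difference of the opposite sign, 0.65 (0.17 to 1.12), with an adjusted p of 0.0881 over the list alone and 0.954 over all probe sets in limma.

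Markers of tissues that a biopsy can include were examined in the same way. The 2 lists under 0.05 before adjustment in camera were both of this kind. The 18 skeletal muscle genes had a median of -0.16 (adjusted p = 0.351 in limma's camera; adjusted p = 0.924 with an estimated correlation), and 14 of them had a lower mean in peri-implantitis. MYL1, TTN and TNNC1, which encode sarcomere proteins, had -0.53 (95% interval -0.92 to -0.15), -0.55 (-0.97 to -0.13) and -0.52 (-0.99 to -0.06), all at means below 7.97. TCAP, another sarcomere gene and 1 of the 2 list members above 7.97, had 0.47 (-0.13 to 1.06). The 7 melanocyte genes had a median of -0.15 (adjusted p = 0.351 in camera; adjusted p = 0.924 with an estimated correlation), among them the pigment cell gene PMEL with -0.55 (-0.98 to -0.13), also at a mean below 7.97. Medians were -0.021 for the 17 salivary gland, 0.0055 for the 10 adipocyte, 0.087 for the 9 Schwann cell and nerve and 0.085 for the 9 erythrocyte genes. EPB42, a red cell membrane protein gene, had 3.61 ± 0.23 (SD, n = 3) and 4.19 ± 0.14 (SD, n = 3), a difference of 0.58 (0.22 to 0.93) with an adjusted p of 0.0443 over the list alone and 0.954 over all probe sets in limma. The haemoglobin gene HBB differed by 0.23 (-0.08 to 0.53).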

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

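Control probe sets that no comparison used were examined for signal. Of the 2197 positive control probe sets, 86.9% had a mean above 7.97, the 95th percentile of the 612 negative ones. Positive controls are meant to give signal, so this share says nothing about the groups. Of the 63 ERCC controls, 2 had a mean above 7.97. Outlying samples were not searched for, since each group held 3 arrays.

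All tests in this paragraph were chosen after the result was seen. The pattern is that the 6 arrays differed no more between the groups than within them, and the tables argue against too little signal on the arrays for epithelial genes: 82.1% of 95 genes on 5 epithelial lists, or 72.8% of 114 with the barrier lipid genes, lay above the 95th percentile of the negative controls, beside 451 of all 782 list genes and 35.4% of all tested probe sets. A candidate explanation is one RNA, or RNA of one makeup, on all 6 arrays: the 307 markers of 20 cell types had a median SD over the arrays of 0.174, which was 0.941 times that of random genes matched on signal and at percentile 3.25 of 10000 random lists. Biopsies of different people with a like makeup cannot be told apart from this. Of the 20 cell type lists, 1 covaried above the 95th percentile of random lists, where chance gives 1. Of the 24 other lists 5 did, bringing the count to 6 of 44 where chance gives 2.2. The 5 principal components of the arrays held between 22.9% and 17.8% of the variance, where equal shares would be 20%. No main direction thus stood out, but what biopsies of different people would give was not tested. That normalization between arrays removed the differences also stays open. A repeated quantile step left 0.981 of an added 2-fold difference. That difference was added to a small share of the normalized probe sets, up and down about equally, where such a step can remove little. The authors' own step was not repeated, as the scanned signals were not used here. Without them it was also not tested whether the values belong to the labelled samples. If they do not, the counts of 0, the interval shares and the values of single genes and lists say nothing about the disease.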

How the results depend on the processing

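The count of 0 called genes and the count of 0 called lists held under every alternative that was run, except that 1 gene, LRRC38, met an unadjusted p under 0.05 with at least a 2-fold difference. The smallest adjusted p ranged from 0.871 to 0.997 over genes and from 0.0761 (without peri-implantitis replicate 2) to 0.924 over lists. The share of probe sets whose interval excluded a 2-fold change, followed through these settings only after the data were seen, lay between 96.7% and 99.6%. Without the dimmest 50% of probe sets, 515 rather than 1028 had an unadjusted p under 0.05, as fewer were tested. Of 84 genes followed through the alternatives, 77 kept the sign of their difference and 7 did not, and none passed the adjusted threshold, the smallest adjusted p being 0.871. With each array left out in turn, the difference ranged from -0.100 to 0.019 for SPRR3, -0.044 to 0.031 for ODAM, -0.040 to 0.078 for JCHAIN, -0.087 to 0.042 for COL1A1, -0.256 to 0.110 for MMP9, -0.114 to 0.059 for IL1B and -0.0205 to 0.056 for MT2A, with no cause tested, and from -1.22 to -0.74 for LRRC38. Leaving out 1 array moved 34 of the 84 values by over 1.5 times, by at most 1.26 standard errors, the 7 above and 27 that kept their sign; FLG ranged from -0.272 to -0.125 and KRT13 from -0.070 to -0.0086. With the quantile normalization repeated, MT2A had -0.062; the cause was not tested. The planned fit without peri-implantitis replicate 4, which also stood for a plate column term, was not run because that sample's column held no values. No paired analysis was possible because the replicate numbers only name samples in order. The 3 arrays against 3 make 10 splits, too few for a share under 0.05: the real split called 0 genes and 0 lists, the highest other split also called 0 genes and 0 lists, and all 10 therefore gave as many. At an unadjusted p under 0.05 the real split had 1028 probe sets and the 9 others 867 to 1421.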

Other observations

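Some gene groups covaried slightly across the 6 arrays, computed regardless of group and chosen after the data were seen. Of the 44 lists, 6 had a mean pairwise correlation of their members above the 95th percentile of 1000 random lists matched on signal, where chance gives 2.2 for independent lists. They were fibrillar collagen and matrix structure (0.151 over 22 genes), MHC class II antigen presentation (0.231 over 10), skeletal muscle (0.132 over 18), the unfolded protein response and secretory pathway (0.142 over 24), chemokines (0.096 over 23) and oxidative phosphorylation (0.111 over 22). The keratinocyte lists did not stand out, with 0.0017 over the 37 genes of the cornified envelope and suprabasal keratins and -0.037 over the 9 basal markers. The correlations were not adjusted for the 44 lists, and genes are not independent replicates. Of the 18 skeletal muscle genes, 2 had a mean above 7.97, so most of that list lay near the signal of the negative controls. The cause of the covariation, technical or otherwise, was not tested for any of the 6 lists.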
